A study of Homo sapiens with 10 samples.

How the data were processed

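mRNA levels were measured on Affymetrix gene arrays in BT549 cells 72 h after transfection with a control siRNA (siControl, 4 arrays), siRNAs against Fra-1 (siFra-1, 3 arrays) or siRNAs against c-Jun (sic-Jun, 3 arrays). The design text calls the replicates biological, and the number of arrays limits the precision. The deposited values are intensities, 1 per probe set and array, on a linear scale, which the authors obtained with PLIER in Affymetrix Expression Console 1.1 per the submitters' processing notes. Background correction, between-array normalization and the annotation used by the authors are not stated. The unit and the linear scale were checked on the values: 33297 probe sets, 0 missing values and 927 values equal to 0. The deposited arrays did not share a distribution, since their upper quartiles ran from 387 to 593.

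Probe sets were joined to genes by gene ID or symbol with the human RefSeq annotation (release GCF_000001405.40, assembly GRCh38.p14), and 19181 probe sets measured a single gene. The 2055 probe sets of several genes and the 12061 without a gene here were left out of the gene tests, because their signal cannot be given to 1 gene. For the 895 genes with several probe sets the brightest was used, which gave 17958 genes. Intensities were transformed as log2(value + 16) and quantile normalised over all probe sets. Fold changes are therefore of intensity plus 16, which shrinks the folds of dim genes.

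Differences were estimated with limma 3.58.1 in R 4.3.3, in 1 linear model of all 10 arrays with group means and no other term, followed by moderated t tests (eBayes with a mean-variance trend). The 3 groups thus shared 1 spread per gene. Yet the median SD between pairs of arrays (dimmest 30% of genes left out) was 0.10 in siFra-1, 0.23 in siControl and 0.25 in sic-Jun. The standard errors and p can therefore misstate the spread of the groups compared, and fits of those groups alone were run beside the model. Each gene was called when its two-sided p, adjusted by the Benjamini-Hochberg method over all genes of a comparison, was under 0.05. Every adjusted p for a gene comes from this limma model. Each log2 fold change is given with its standard error from the model, and group levels with their SD. The comparisons were siFra-1 against siControl, sic-Jun against siControl and siFra-1 against sic-Jun. The first pair share the control arrays, so their overlap was set beside expected numbers for independent calls and their correlation beside 50 simulations without effect (independent genes, array-wide deviations drawn with replacement, and, added after the data were seen, drawn once each), and both beside 6 ways of splitting the controls into separate pairs.

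A total of 21 gene lists were tested with camera (preset inter-gene correlation 0.01), adjusted over the 21 lists of a comparison. They were the AP-1 family, mesenchymal factors, epithelial junction and keratin genes, invasion proteases and inhibitors, integrins and focal adhesion, collagens and matrix, EGFR ligands and MAPK feedback, cytokines and NF-kB targets, interferon response, TGF-beta pathway, unfolded protein response, hypoxia and glycolysis, mitosis, G1/S and DNA replication, CDK inhibitors and p53 targets, sterol synthesis, apoptosis regulators, luminal breast markers, leukocyte markers, endothelial markers and reference genes. Of 443 places on these lists 404 were measured. The other 39 had no probe set that measured them alone. In all, 4 measured genes were on more than 1 list, among them KRT8 and KRT18 (epithelial and luminal) and XBP1 (luminal and unfolded protein response). Camera with a correlation estimated from the data and fry, a rotation test, were run beside it. Camera asks whether a list shifted more than the other genes did, and fry whether it shifted at all. Numbers adjusted over the list alone count members that pass when only that list is adjusted.

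The genes named were chosen by rule: the AP-1 family members that passed; genes tied to the study's subject whatever their result; the 10 largest rises and falls of each knockdown (5 between the knockdowns) among called genes whose groups' arrays did not overlap; up to 4 members with the smallest adjusted p from each list; and the 5 genes in each direction with the largest change common to both knockdowns. A few genes that this rule names are not reported here. The genes in opposite directions, CD14, TEK and other single members that make up a count of 5 or fewer were named after their values were seen.

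The lists, the rule, the tests and most alternatives were fixed before the data were examined. An exception is the normalization: the plan held the log2 values as deposited as the main setting and quantile normalization as an alternative. Quantile normalization became the main setting once the unequal distributions were seen and before any test, in a step that also looked at the levels of FOSL1 and JUN. The added alternatives were no between-array normalization, arrays of position columns 7 and 9 alone, and the list tests under median centring and with the position column as a block. The position column is the number that ends a sample description (5, 7 or 9, missing for sic-Jun replicate 1), and its meaning is not stated. Column 5 held siControl replicates 1 and 3 and no knockdown array. Column 7 held siControl replicate 2, siFra-1 replicates 1 and 2 and sic-Jun replicate 2. Column 9 held siControl replicate 4, siFra-1 replicate 3 and sic-Jun replicate 3. The other alternatives were no mean-variance trend, a robust fit, median centring, leaving out the dimmest 30% of genes, the mean of a gene's probe sets, every probe set by itself, a 1.5-fold minimum, an offset of 1, fits of the compared groups alone, siControl replicates 2 and 3 (both numbered 2 in their descriptions) averaged, blocks on the title number, the description number or the position column, array weights, and each array of the compared groups left out in turn. The replicate numbers were not used to pair arrays.

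The model was tested on simulated data for siFra-1 against siControl. The noise was drawn independently for each gene, so the share of false calls below does not cover the array-wide deviations of the real arrays. Of 200 genes given a change in 5 runs, 59.2% of changes of 0.4 and 99.4% of changes of 1 on the log2 scale were called, and 5.15% of the calls were false.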

Results

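BT549, an established human cell line derived from a triple-negative breast cancer, was transfected with a control siRNA, with a pool of siRNAs against Fra-1 or with a pool against c-Jun. Fra-1 and c-Jun, the products of FOSL1 and JUN, are subunits of the dimeric transcription factor AP-1, and the study concerned AP-1 and the invasiveness of this type of cancer. RNA was taken 72 h after transfection and mRNA levels were measured on Affymetrix gene arrays. The 10 arrays comprised 4 of siControl, 3 of siFra-1 and 3 of sic-Jun, which the submitters' design text calls biological replicates. Levels of 17958 genes were compared. The upper quartile of the deposited intensities ran from 387 in siControl replicate 4 to 593 in siControl replicate 1, and the median from 64.6 to 89.7. The number of arrays limited the precision. The SD of the log2 differences across genes was taken between pairs of normalised arrays of 1 group, without the dimmest 30% of genes. It was 0.09 to 0.11 in siFra-1, 0.11 to 0.27 in siControl and 0.13 to 0.32 in sic-Jun.

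The targeted gene was lower in every array of its own knockdown. FOSL1 stood at normalised intensities of 979, 861, 1221 and 901 in siControl replicates 1 to 4, at 394, 369 and 363 in siFra-1 replicates 1 to 3, and at 923, 885 and 897 in sic-Jun replicates 1 to 3. JUN stood at 1706, 1687, 1833 and 1638 in siControl, at 1969, 1980 and 1930 in siFra-1, and at 864, 883 and 874 in sic-Jun. FOSL1 fell 2.55-fold with siFra-1 (log2 fold change -1.35 ± 0.10 SE, n = 3 against 4, limma adjusted p = 1.6e-06) and differed by -0.12 ± 0.10 with sic-Jun (adjusted p = 0.50). JUN fell 1.95-fold with sic-Jun (-0.96 ± 0.05, adjusted p = 8.5e-08). With siFra-1, JUN was 0.19 ± 0.05 higher (adjusted p = 0.014), a call that was lost without siFra-1 replicate 1 (adjusted p = 0.069), replicate 2 (0.083) or replicate 3 (0.052), under median centring (0.068), without between-array normalization (1.0) and with the replicate number as a block (0.072). Within the arrays whose descriptions share position column 7 or 9, FOSL1 differed by -1.14 and -1.27 with siFra-1 and JUN by -0.92 and -0.89 with sic-Jun.

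**Figure D1:**
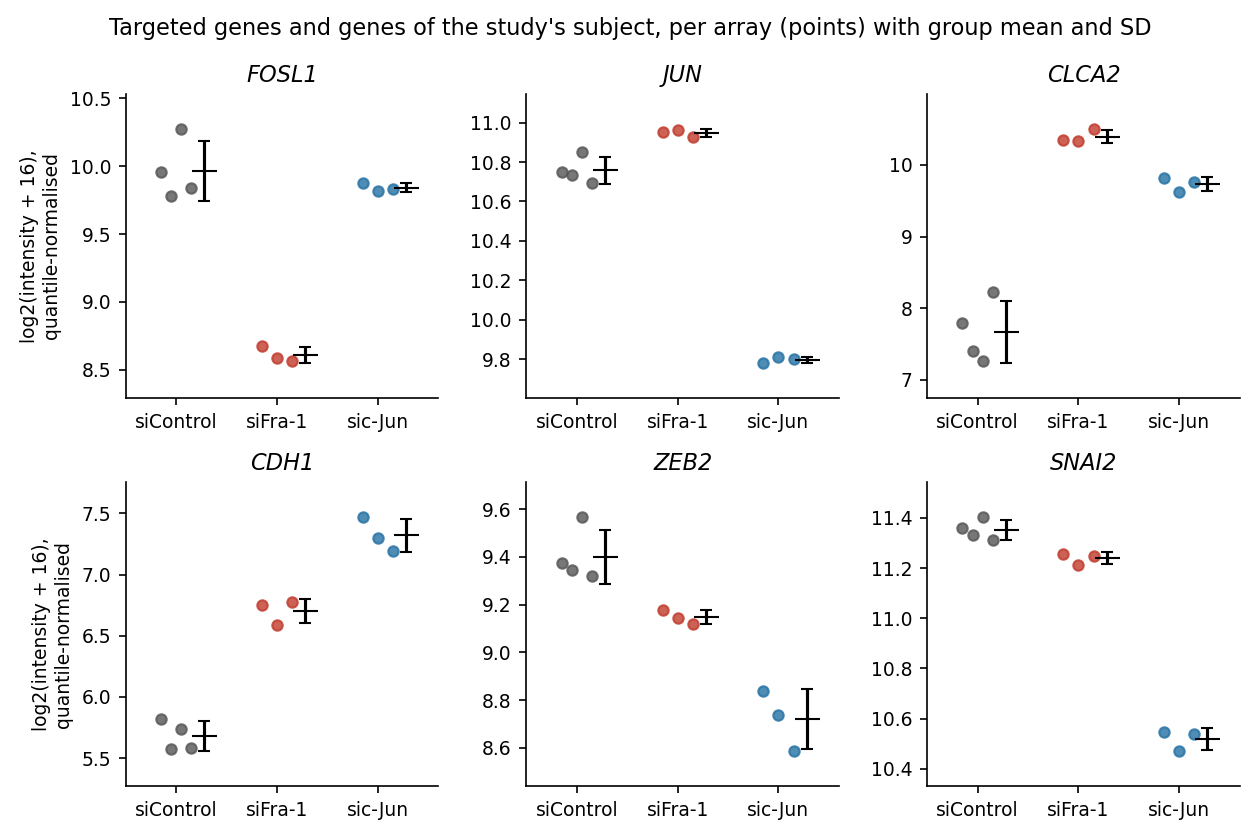
Level of 6 genes in each array (points, log2 of the quantile-normalised intensity plus 16) with the group mean and SD beside them, for 4 siControl, 3 siFra-1 and 3 sic-Jun arrays. FOSL1 was low in siFra-1 alone (363 to 394 against 861 to 1221 in siControl) and JUN in sic-Jun alone, while CLCA2 and CDH1 were higher in both knockdowns; each panel has its own axis, which does not start at 0.

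Fra-1 knockdown was compared with the control siRNA to see which mRNAs depended on Fra-1 in these cells. CLCA2, a regulator of chloride conductance in epithelial cells, rose 6.62-fold (log2 fold change 2.73 ± 0.17, n = 3 against 4, adjusted p = 6.2e-07). CDH1, the E-cadherin of epithelial adherens junctions, rose 2.04-fold (1.03 ± 0.10, adjusted p = 3.0e-05), from an intensity of 35.2 to 88.3. The fold is of intensity plus 16, so it is smaller than the ratio of these intensities. In siControl CDH1 was dimmer than the median gene (log2 level 5.68 against 7.54). The chemokines CXCL8 and CCL5 rose 3.16-fold (1.66 ± 0.08) and 3.13-fold (1.65 ± 0.07). NPNT, nephronectin, a matrix ligand of integrins, fell 4.02-fold (-2.01 ± 0.09, adjusted p = 6.3e-08). In all, 2218 of 17958 genes passed, 1131 higher and 1087 lower, of which 340 changed at least 1.5-fold (228 higher and 112 lower).

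Among the other largest rises with siFra-1 were HPD, an enzyme of tyrosine breakdown (1.99 ± 0.16), ADGRG6, an adhesion G protein-coupled receptor (1.70 ± 0.07), VDR, the vitamin D receptor (1.68 ± 0.11), and complement C3 (1.61 ± 0.10). INHBA, a subunit of activin A (1.52 ± 0.09), RGS5, a regulator of G protein signalling (1.52 ± 0.12), and KCNIP1 (1.47 ± 0.13) followed. The largest falls after NPNT were in the chromatin organiser SATB1 (-1.44 ± 0.11), the cationic amino acid transporter SLC7A2 (-1.42 ± 0.10), the neurotrophin receptor NTRK2 (-1.40 ± 0.07), BAALC (-1.35 ± 0.06), FOSL1 itself, TXNIP (-1.34 ± 0.09) and the T-box factor EOMES (-1.29 ± 0.10). PDGFRL (-1.13 ± 0.12) and RTL9 (-1.10 ± 0.11) completed the set. CLCA2 differed by 2.94 and 2.28 within position columns 7 and 9. Without between-array normalization 284 genes passed, 68.0% of them higher against 51.0% with quantile normalization. In all, 4830 passed with array weights and 4369 with arrays of position columns 7 and 9 alone. Leaving out siFra-1 replicate 1, 2 or 3 left 1309, 1221 or 1282 genes, and leaving out siControl replicate 3 gave 3340.

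Of the genes tied to the study's subject, PLAU, the protease urokinase, rose with siFra-1 (0.44 ± 0.05, adjusted p = 3.5e-05), and CCND1, cyclin D1, rose (0.56 ± 0.08, adjusted p = 3.1e-04), though the mean of the 2 probe sets of CCND1 did not pass (0.36, adjusted p = 0.14). The CDH1 repressors ZEB1 (-0.16 ± 0.05, adjusted p = 0.044) and ZEB2 (-0.25 ± 0.08, adjusted p = 0.046) passed narrowly, and SNAI2 (-0.11 ± 0.04, adjusted p = 0.089), VIM, the intermediate filament vimentin (-0.08 ± 0.03, adjusted p = 0.15), and PLAUR, the urokinase receptor (-0.04 ± 0.06, adjusted p = 0.81), did not pass. The call on ZEB1 was lost without siControl replicate 1 (adjusted p = 0.11), 2 (0.087) or 4 (0.076) and without siFra-1 replicate 1 (0.15), 2 (0.14) or 3 (0.15). The call on ZEB2 was lost without siControl replicate 1 (0.076), 2 (0.058) or 4 (0.053) and without siFra-1 replicate 1 (0.12), 2 (0.16) or 3 (0.17). MMP1, a collagenase, passed at 0.59 ± 0.16 (adjusted p = 0.030), which was lost without siControl replicate 2 (0.071) or 4 (0.055) and without siFra-1 replicate 1 (0.15), 2 (0.077) or 3 (0.073). Median centring also ended the calls on ZEB1 (0.41) and ZEB2 (0.16).

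Of 21 gene lists fixed before the data were examined, 11 passed with siFra-1 against siControl, 9 higher and 2 lower. Of these, 3, all higher, passed with an estimated correlation. The 23 measured interferon response genes, most of them antiviral effectors, included 16 that rose, 0 that fell and 7 that did not pass (19 and 0 past the threshold when adjusted over the list alone). MX1 (1.43 ± 0.12), OAS2 (1.08 ± 0.11) and IFIT1 (0.90 ± 0.11) were examples. The interferon list was higher (adjusted p = 2.1e-15, or 0.060 with an estimated correlation). Of 21 cytokines and NF-kB target genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone), among them IL6 (1.01 ± 0.08), CCL2 (0.66 ± 0.05) and the chemokines CXCL8 and CCL5 given above. That list was higher (adjusted p = 4.9e-11, or 0.027 with an estimated correlation). Of 19 genes of the unfolded protein response, 11 rose and 0 fell (13 and 0 adjusted over the list alone), and the list was higher (adjusted p = 2.4e-11, or 0.016 with an estimated correlation). The largest were CHAC1 (1.12 ± 0.11), TRIB3 (0.76 ± 0.07) and ASNS (0.55 ± 0.07), which are known as targets of ATF4, and the chaperone gene HSPA5 rose by 0.26 ± 0.03. Of 21 epithelial junction and keratin genes, 7 rose and 1 fell (8 and 2 adjusted over the list alone), and the list was higher (adjusted p = 4.6e-05, or 0.027 with an estimated correlation). The keratins KRT7 (1.29 ± 0.08), KRT8 (1.24 ± 0.07) and KRT18 (1.09 ± 0.06) rose and the desmosomal DSP fell (-0.79 ± 0.10).

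Among 24 genes of the TGF-beta pathway, 12 rose and 1 fell with siFra-1 (15 and 2 adjusted over the list alone), with INHBA given above, BMP4 (0.67 ± 0.05) and CCN1 (0.62 ± 0.07) as examples. The list was higher (adjusted p = 6.6e-10, or 0.060 with an estimated correlation). Of 23 mitosis genes, 0 rose and 12 fell (0 and 15 adjusted over the list alone), and the list was lower (adjusted p = 9.4e-09, or 0.060 with an estimated correlation). UBE2C (-0.35 ± 0.04), AURKB (-0.34 ± 0.06) and CENPA (-0.30 ± 0.06) were examples. Of 17 hypoxia and glycolysis genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.0033, or 0.15 with an estimated correlation), among them EGLN3 (0.62 ± 0.08) and ANGPTL4 (0.53 ± 0.06). Of 17 luminal breast markers, 4 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.021, or 0.28 with an estimated correlation). The largest rises were those of KRT8 and KRT18, also on the epithelial list. The prolactin receptor PRLR was at 0.34 ± 0.05 and XBP1, also on the unfolded protein response list, at 0.24 ± 0.06. The median of the luminal list was 0.02. Of 18 CDK inhibitors and p53 target genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.022, or 0.20 with an estimated correlation). The largest of these were the apoptosis gene PMAIP1 (1.04 ± 0.11) and the stress gene SESN2 (0.57 ± 0.11), neither of which encodes a CDK inhibitor.

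Of 19 mesenchymal genes, 2 rose and 6 fell with siFra-1 (4 and 10 adjusted over the list alone, adjusted p = 0.038, or 0.55 with an estimated correlation). ACTA2, smooth muscle actin (-0.98 ± 0.04), and the transcription factors PRRX1 (-0.77 ± 0.09) and TWIST1 (-0.53 ± 0.07) fell, while CDH2, N-cadherin, rose (0.60 ± 0.05). The call on that list was lost without siControl replicate 3 (adjusted p = 0.086), under median centring (0.066), without between-array normalization (0.10), with the position column as a block (0.16), with a block on the title number (0.057) or the description number (0.058), without dim genes (0.078) and with arrays of position columns 7 and 9 alone (0.11). Of 21 invasion proteases and inhibitors, 7 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.042, or 0.38 with an estimated correlation). The protease ADAMTS1 (0.91 ± 0.11) and heparanase, HPSE (0.46 ± 0.05), rose and the gelatinase MMP2 fell (-0.55 ± 0.05). This call was lost without siControl replicate 1 (adjusted p = 0.11), 2 (0.057) or 4 (0.051) and without siFra-1 replicate 3 (0.11, with a median of -0.01 in place of 0.02), as it was without dim genes (0.054), with siControl replicates 2 and 3 averaged (0.051) and with the title number as a block (0.057).

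The other 10 lists did not pass with siFra-1. Of 18 measured members of the AP-1 family, 3 were higher and 2 lower (5 and 3 adjusted over the list alone, list adjusted p = 0.63): FOSL1 and JUN as above, ATF2 (-0.28 ± 0.05), ATF4 (0.24 ± 0.04) and JUNB (0.29 ± 0.09, adjusted p = 0.046). The mean of the probe sets of ATF4 did not pass (0.05, adjusted p = 0.68), and the call on JUNB was lost without siControl replicate 1 (0.11), 2 (0.10) or 4 (0.12) and without siFra-1 replicate 1 (0.17), 2 (0.12) or 3 (0.11). The AP-1 list had a median of 0.05, a mean of -0.0031 and a negative direction by fry. Among 18 integrin and focal adhesion genes, 4 were higher and 1 lower (7 and 2 adjusted over the list alone, list adjusted p = 0.17), with the integrin subunit genes ITGB8 at 1.43 ± 0.14 and ITGB5 at 0.66 ± 0.07. Among 21 collagen and matrix genes, 4 were higher and 5 lower (7 and 5 adjusted over the list alone, list adjusted p = 0.54), with COL1A1 at 0.57 ± 0.11 and LAMB3 at -0.55 ± 0.12. Among 22 EGFR ligands and MAPK feedback genes, 7 were higher and 2 lower (7 and 3 adjusted over the list alone, list adjusted p = 0.15). The ligand gene HBEGF was at 1.33 ± 0.10 and EGR1, an immediate early transcription factor, at -0.84 ± 0.09. This list passed without siControl replicate 3 (adjusted p = 0.032). With the position column as a block or arrays of position columns 7 and 9 alone, the integrin (adjusted p = 0.039 and 0.036) and EGFR lists (0.017 and 0.023) passed, as did the collagen list with those arrays (0.049).

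Among the remaining lists of siFra-1 against siControl, 2 of 27 genes of G1/S and DNA replication were higher and 1 lower (2 and 1 adjusted over the list alone, list adjusted p = 0.87). In sterol synthesis, 3 of 15 genes were higher and 1, LSS (-0.38 ± 0.07), lower (4 and 2 adjusted over the list alone, list adjusted p = 0.27). In apoptosis regulators, 1 of 21 was higher and 2 lower (1 and 2 adjusted over the list alone, list adjusted p = 0.87), with BCL2L11 at -0.39 ± 0.08. Their median was 0.07, their mean -0.0039 and their fry direction negative. Of 15 leukocyte markers, 1, CD14, was higher (1.05 ± 0.09) and 0 lower (1 and 0 adjusted over the list alone, list adjusted p = 0.54). Of 12 endothelial markers, 0 were higher and 0 lower (0 and 0 adjusted over the list alone, list adjusted p = 0.54). In the control arrays 1 of the 15 leukocyte and 1 of the 12 endothelial markers were brighter than the median gene. Of 12 reference genes, 2 were higher and 1 lower (2 and 1 adjusted over the list alone, list adjusted p = 0.35), with the transferrin receptor TFRC at 0.39 ± 0.04. The reference list passed by fry (adjusted p = 0.0023).

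**Figure D2:**
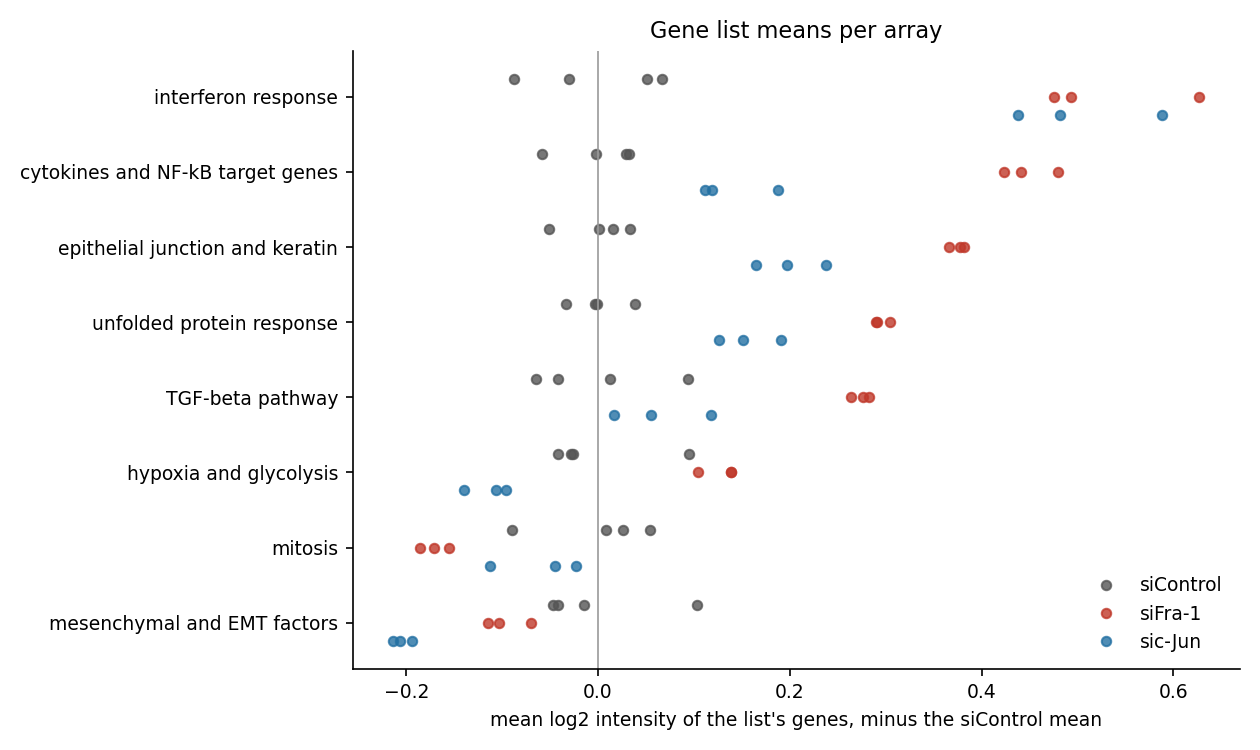
Mean log2 intensity of the genes of 8 lists in each array, minus the siControl mean, for 4 siControl, 3 siFra-1 and 3 sic-Jun arrays (1 point per array, quantile-normalised). For the interferon list the siFra-1 arrays lay between 0.48 and 0.63 and the sic-Jun arrays between 0.44 and 0.59; for hypoxia and glycolysis the knockdowns lay on opposite sides of 0, and without between-array normalization, where all genes had a median of 0.09 with sic-Jun, the medians of that list (0.08) and of the mesenchymal list (0.04) were positive but below it. The median of the mitosis list with sic-Jun turned positive under median centring (0.03) and without between-array normalization (0.18).

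The knockdown of c-Jun was compared with the control siRNA to see which mRNAs depended on c-Jun. RGS5 rose 6.94-fold (log2 fold change 2.79 ± 0.12, n = 3 against 4, adjusted p = 3.2e-08), ADGRG6 rose 4.44-fold (2.15 ± 0.07) and CLCA2 rose 4.19-fold (2.07 ± 0.17). CDH1, E-cadherin, rose 3.12-fold (1.64 ± 0.10, adjusted p = 5.5e-07), from an intensity of 35.2 to 144. This fold, too, is of intensity plus 16 and is smaller than the ratio of the intensities. With sic-Jun the log2 level of CDH1 was 7.32, still under that of the median gene in siControl (7.54). The CDH1 repressors SNAI2 (-0.83 ± 0.04, adjusted p = 8.5e-08) and ZEB2 (-0.68 ± 0.08, adjusted p = 6.4e-05) fell. NTRK2, the receptor of the neurotrophin BDNF, fell 3.20-fold (-1.68 ± 0.07). In all, 2005 of 17958 genes passed, 932 higher and 1073 lower, of which 376 changed at least 1.5-fold (191 higher and 185 lower).

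Other large rises with sic-Jun included those of the carboxypeptidases CPM (1.84 ± 0.09) and CPA4 (1.67 ± 0.09), VDR (1.70 ± 0.11), PADI2 (1.59 ± 0.11) and the interleukin receptor IL7R (1.48 ± 0.08). The largest falls included SLC7A2 (-1.66 ± 0.10), the growth factor BMP6 (-1.43 ± 0.13), the Notch ligand JAG1 (-1.43 ± 0.08), DSP (-1.42 ± 0.10), EOMES (-1.36 ± 0.10), the heparan sulfatase SULF2 (-1.36 ± 0.11), NPNT (-1.34 ± 0.09), DDIT4L (-1.33 ± 0.14) and KHDRBS3 (-1.31 ± 0.08). CDH1 differed by 1.72 and 1.61, and ZEB2 by -0.61 and -0.73, within position columns 7 and 9. The share of higher genes moved from 46.5% to 59.3% under median centring and to 82.9% without between-array normalization, where 579 genes passed. With the position column as a block 962 passed, with the arrays of these 2 groups alone 1221, with array weights 7452, with arrays of position columns 7 and 9 alone 3534, and without sic-Jun replicate 2 the count was 1144.

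Of the other genes tied to the study's subject, PLAU rose with sic-Jun (0.38 ± 0.05, adjusted p = 1.1e-04). MMP1 (0.37 ± 0.16, adjusted p = 0.18) and CCND1 (0.19 ± 0.08, adjusted p = 0.15) did not pass. MMP1 passed without sic-Jun replicate 3 (0.56, adjusted p = 0.032), and CCND1 passed without siControl replicate 3 (0.26, adjusted p = 0.0015). ZEB1 (-0.16 ± 0.05, adjusted p = 0.042), VIM (-0.13 ± 0.03, adjusted p = 0.024) and PLAUR (-0.20 ± 0.06, adjusted p = 0.044) passed. Without between-array normalization, where the median of all genes was 0.09, they were at 0.06, 0.08 and 0.01 and did not pass, and under median centring none of the 3 passed (adjusted p = 0.55, 0.52 and 0.40). ZEB1 was also lost without siControl replicate 1 (0.098), 2 (0.078) or 4 (0.075) and without sic-Jun replicate 2 (0.19) or 3 (0.14). VIM was lost without siControl replicate 4 (0.062) and without sic-Jun replicate 2 (0.11) or 3 (0.085). PLAUR was lost without siControl replicate 1 (0.085) and without sic-Jun replicate 2 (0.20) or 3 (0.12). Without between-array normalization ZEB2 did not pass either (-0.47, adjusted p = 0.18).

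With sic-Jun 6 of the 21 lists passed, 5 higher and 1 lower. With an estimated correlation 0 passed (3 had an unadjusted p under 0.05), and 8 passed by fry. Of 23 interferon response genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone), among them IFI44L (1.30 ± 0.13), MX1 (1.09 ± 0.12) and RSAD2 (0.88 ± 0.10). The interferon list was higher (adjusted p = 2.2e-14, or 0.17 with an estimated correlation). Of 19 mesenchymal genes, 1 rose and 11 fell (1 and 11 adjusted over the list alone), among them SNAI2, fibronectin FN1 (-0.65 ± 0.06) and PRRX1 (-0.61 ± 0.09), with CDH2 the one that rose (0.60 ± 0.05). The mesenchymal list was lower (adjusted p = 2.8e-04, or 0.40 with an estimated correlation), but without between-array normalization its median was 0.04 in place of -0.16, against 0.09 for all genes, and it did not pass (adjusted p = 0.096). Of 19 genes of the unfolded protein response, 4 rose and 0 fell (10 and 0 adjusted over the list alone, adjusted p = 6.6e-04, or 0.17 with an estimated correlation), CHAC1 (0.75 ± 0.11) and ASNS (0.45 ± 0.07) the largest that held with any array of these groups left out. Of 21 cytokines and NF-kB target genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.0060, or 0.30 with an estimated correlation). CCL5 (1.19 ± 0.07), CXCL8 (0.81 ± 0.08) and CCL2 (0.68 ± 0.05) rose and the prostaglandin synthase PTGS2 fell (-0.79 ± 0.10).

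Of 21 epithelial junction and keratin genes, 6 rose and 2 fell with sic-Jun (6 and 2 adjusted over the list alone, adjusted p = 0.019, or 0.20 with an estimated correlation). KRT7 (1.20 ± 0.08), KRT18 (0.51 ± 0.06) and KRT8 (0.46 ± 0.07) rose beside CDH1 and CLCA2, and DSP fell. The call was lost without sic-Jun replicate 3 (adjusted p = 0.073, with a median of -0.03 in place of 0.04), without between-array normalization (0.079) and under median centring (0.10, with a median of -0.08). Of 24 TGF-beta pathway genes, 8 rose and 5 fell (9 and 6 adjusted over the list alone, adjusted p = 0.043, or 0.67 with an estimated correlation). INHBA (0.83 ± 0.09), CCN1 (0.66 ± 0.07) and BMP4 (0.60 ± 0.05) rose and LTBP1, which binds latent TGF-beta, fell (-0.57 ± 0.06). That list was lost without siControl replicate 2 (adjusted p = 0.054) or 4 (0.073), without sic-Jun replicate 1 (0.075) or 3 (0.055), without dim genes (0.088), with the title number as a block (0.069) and by fry (0.10).

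The other 15 lists did not pass with sic-Jun. In the AP-1 family 0 of 18 were higher and 1, JUN, lower (0 and 1 adjusted over the list alone, list adjusted p = 0.10). Of 21 invasion proteases and inhibitors 3 were higher and 6 lower (4 and 7 adjusted over the list alone, list adjusted p = 0.45), with the membrane protease MMP14 at -0.54 ± 0.07 and its regulator TIMP2 at -0.48 ± 0.05. Of 21 collagen and matrix genes 2 were higher and 6 lower (2 and 6 adjusted over the list alone, list adjusted p = 0.097), with LAMB3 at -0.84 ± 0.12 and tenascin TNC at -0.73 ± 0.06. The list passed without siControl replicate 2 (adjusted p = 0.034). Of 18 integrin and focal adhesion genes 4 were higher and 1 lower (6 and 1 adjusted over the list alone, list adjusted p = 0.25), with ITGB8 at 1.17 ± 0.14 and ITGB3 at -0.84 ± 0.12. Of 22 EGFR ligands and MAPK feedback genes 3 were higher and 7 lower (4 and 9 adjusted over the list alone, list adjusted p = 0.12), with EGR1 at -1.07 ± 0.09. Of 17 hypoxia and glycolysis genes 2 were higher and 4 lower (3 and 7 adjusted over the list alone, list adjusted p = 0.10), with NDRG1 at -0.56 ± 0.07. That list passed without siControl replicate 3 (adjusted p = 0.043). Of 23 mitosis genes 0 were higher and 4 lower (0 and 4 adjusted over the list alone, list adjusted p = 0.12), with UBE2C at -0.36 ± 0.04. This list, too, passed without siControl replicate 3 (adjusted p = 0.0020).

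Among 18 CDK inhibitors and p53 target genes 5 were higher and 2 lower with sic-Jun (5 and 4 adjusted over the list alone, list adjusted p = 0.47), with PMAIP1 at 0.90 ± 0.11 and the CDK inhibitor gene CDKN1A at -0.66 ± 0.08. In G1/S and DNA replication 3 of 27 were higher and 1, E2F7 (-0.41 ± 0.08), lower (3 and 1 adjusted over the list alone, list adjusted p = 0.51). In sterol synthesis 2 of 15 were higher and 0 lower (4 and 1 adjusted over the list alone, list adjusted p = 0.097), and the list passed without siControl replicate 3 (adjusted p = 0.035). In apoptosis regulators 3 of 21 were higher and 3 lower (4 and 3 adjusted over the list alone, list adjusted p = 0.88). Among luminal breast markers 2 of 17, KRT8 and KRT18, were higher and 0 lower (2 and 0 adjusted over the list alone, list adjusted p = 0.45). Among leukocyte markers 0 of 15 were higher and 1 lower (0 and 1 adjusted over the list alone, list adjusted p = 0.69), and among endothelial markers 1 of 12, the receptor gene TEK (0.90 ± 0.12), was higher and 0 lower (1 and 0 adjusted over the list alone, list adjusted p = 0.88). Among reference genes 1 of 12, TFRC (0.25 ± 0.04), was higher and 1 lower (1 and 1 adjusted over the list alone, list adjusted p = 0.47). Median and mean differed in sign for the integrin (-0.02 and 0.07), endothelial (-0.08 and 0.02), CDK inhibitor (-0.0039 and 0.03) and reference lists (-0.0031 and 0.02), and the test's direction was positive against a negative median for G1/S (-0.01) and apoptosis genes (-0.04). Under median centring the integrin (adjusted p = 0.034) and sterol lists (0.011) passed. By fry the AP-1, sterol and hypoxia lists passed (0.037 each). The AP-1 list holds JUN, the siRNA target and its 1 called member, so part of its shift follows from the knockdown itself. The mitosis list passed with the position column as a block (0.019), and the mitosis (0.0033) and hypoxia lists (0.042) with arrays of position columns 7 and 9 alone.

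The knockdowns were compared with each other to see whether they differed gene by gene. HBEGF, a ligand of the EGF receptor, was 3.31-fold higher with siFra-1 than with sic-Jun (log2 difference 1.73 ± 0.11, n = 3 against 3, adjusted p = 1.1e-06). The epithelial transcription factor ELF3 (1.37 ± 0.11), the proteoglycan gene BGN (1.36 ± 0.07), the growth factor binding protein gene IGFBP4 (1.33 ± 0.09) and DIO3, a thyroid hormone deiodinase (1.29 ± 0.11), were also higher with siFra-1. CPM (-1.31 ± 0.10), RGS5 (-1.28 ± 0.13), CPA4 (-1.27 ± 0.09), FOSL1 (-1.23 ± 0.10) and FGF1 (-1.20 ± 0.10) were lower, and JUN was 1.15 ± 0.05 higher. SNAI2 (0.72 ± 0.04, adjusted p = 8.3e-07) and ZEB2 (0.43 ± 0.08, adjusted p = 0.0073) were higher and CDH1 (-0.61 ± 0.11, adjusted p = 0.0053) lower with siFra-1. In all, 947 genes passed, 603 higher and 344 lower with siFra-1, and 192 of them differed at least 1.5-fold (127 higher and 65 lower).

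Of the remaining genes tied to the subject, CCND1 was 0.38 ± 0.08 higher with siFra-1 than with sic-Jun (adjusted p = 0.016), while CLCA2 (0.66 ± 0.18, adjusted p = 0.059), ZEB1 (0.00 ± 0.05), VIM (0.05 ± 0.04), MMP1 (0.22 ± 0.17), PLAU (0.06 ± 0.05) and PLAUR (0.16 ± 0.06) did not pass. CCND1 was lost without siFra-1 replicate 1 (adjusted p = 0.092) or 2 (0.086) and without sic-Jun replicate 2 (0.070) or 3 (0.055). The AP-1 genes ATF3 (0.61 ± 0.15, adjusted p = 0.033) and MAFF (0.50 ± 0.10, adjusted p = 0.012) passed. ATF3 was lost without siFra-1 replicate 1 (0.15), 2 (0.080) or 3 (0.13) and without sic-Jun replicate 2 (0.089) or 3 (0.10), and MAFF without siFra-1 replicate 1 (0.080) and without sic-Jun replicate 2 (0.065) or 3 (0.051). With the mean of its probe sets ZEB2 did not pass (0.14, adjusted p = 0.61), nor did CCND1 (0.44, adjusted p = 0.15). Without between-array normalization the median difference of all genes was -0.10 and 106 genes passed, 28.3% of them higher against 63.7%. Relative to that median SNAI2 (0.52, adjusted p = 0.30) and ZEB2 (0.23, adjusted p = 0.71) were on the same side. The count was 623 under median centring, 2084 with these 2 groups alone, 1939 with siControl replicates 2 and 3 averaged, 8486 with array weights and 3639 with arrays of position columns 7 and 9 alone. Without siFra-1 replicate 1, 2 or 3 it was 469, 469 or 501, and without sic-Jun replicate 2 it was 514.

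Between the knockdowns 11 lists passed, 10 higher and 1 lower with siFra-1. With an estimated correlation 0 passed (6 had an unadjusted p under 0.05), and 13 passed by fry. Of 21 cytokines and NF-kB target genes 9 were higher and 0 lower (11 and 0 adjusted over the list alone, adjusted p = 3.2e-08, or 0.064 with an estimated correlation), with IL6 at 1.12 ± 0.08 and CXCL8 at 0.85 ± 0.09. Of 17 hypoxia and glycolysis genes 5 were higher and 0 lower (11 and 0 adjusted over the list alone, adjusted p = 3.2e-08, or 0.064 with an estimated correlation), with NDRG1 at 0.86 ± 0.08. Without between-array normalization that list's median was -0.01 in place of 0.19, still above the median of all genes (-0.10), and the list still passed. Of 24 TGF-beta pathway genes 8 were higher and 0 lower (10 and 0 adjusted over the list alone, adjusted p = 1.0e-05, or 0.15 with an estimated correlation), with TGFB2 at 0.84 ± 0.06. The median was -0.07 in place of 0.12 in that setting, also above that of all genes, and the list still passed. Of 22 EGFR ligands and MAPK feedback genes 6 were higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 2.8e-05, or 0.40 with an estimated correlation). Of 19 genes of the unfolded protein response 7 were higher and 0 lower (9 and 1 adjusted over the list alone, adjusted p = 3.7e-05, or 0.066 with an estimated correlation), with TRIB3 at 0.55 ± 0.08. Without between-array normalization the median was -0.04 and the call was lost (adjusted p = 0.40).

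Of 23 mitosis genes 0 were higher and 0 lower between the knockdowns (0 and 0 adjusted over the list alone), yet the list was lower with siFra-1 (median -0.11, adjusted p = 2.3e-06, or 0.14 with an estimated correlation). Of 21 invasion proteases and inhibitors 6 were higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 4.6e-04, or 0.15 with an estimated correlation), with HPSE at 0.78 ± 0.06. Without between-array normalization the median was -0.03 and the call was lost (adjusted p = 0.056). Of 21 collagen and matrix genes 6 were higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.0013, or 0.47 with an estimated correlation; fry adjusted p = 0.055), with COL1A1 at 0.85 ± 0.12. Of 21 epithelial junction and keratin genes 4 were higher and 1, CDH1, lower (6 and 1 adjusted over the list alone, adjusted p = 0.0052, or 0.11 with an estimated correlation), with KRT8 at 0.79 ± 0.08 and KRT18 at 0.58 ± 0.07. Of 17 luminal breast markers 4 were higher and 0 lower (4 and 0 adjusted over the list alone, adjusted p = 0.010, or 0.27 with an estimated correlation), and with the position column as a block the list did not pass (adjusted p = 0.051). Of 19 mesenchymal genes 6 were higher and 1, ACTA2 (-1.05 ± 0.04), lower (7 and 3 adjusted over the list alone, adjusted p = 0.030, or 0.47 with an estimated correlation). The mesenchymal call was lost by fry (adjusted p = 0.055), under median centring (0.36), with arrays of position columns 7 and 9 alone (0.060) and without between-array normalization (0.66, with a median of -0.14 in place of 0.05).

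The other 10 lists did not pass between the knockdowns. Of 23 interferon response genes 0 were higher and 1, RSAD2 (-0.39 ± 0.10), lower (0 and 1 adjusted over the list alone, list adjusted p = 0.79). In the AP-1 family 3 of 18 were higher and 1 lower (6 and 2 adjusted over the list alone, list adjusted p = 0.067), and the list passed without siFra-1 replicate 3 (adjusted p = 0.0498). Of 18 integrin and focal adhesion genes, 1 was higher and 0 lower (3 and 0 adjusted over the list alone, list adjusted p = 0.62). Of 18 CDK inhibitors and p53 target genes, 2 were higher and 0 lower (3 and 0 adjusted over the list alone, list adjusted p = 0.096), with CDKN1A at 0.75 ± 0.08. In G1/S and DNA replication 1 of 27 was higher and 1 lower (1 and 1 adjusted over the list alone, list adjusted p = 0.46), with a median of 0.01 and a negative direction by the test. In sterol synthesis 0 of 15 were higher and 0 lower (0 and 0 adjusted over the list alone, list adjusted p = 0.45), and in apoptosis regulators 1 of 21 was higher and 1 lower (2 and 2 adjusted over the list alone, list adjusted p = 0.95), with a median of 0.02 and a negative direction by the test. Among leukocyte markers 1 of 15, CD14 (0.97 ± 0.10), was higher and 0 lower (1 and 0 adjusted over the list alone, list adjusted p = 0.16), and among endothelial markers 0 of 12 were higher and 1, TEK (-0.56 ± 0.12), lower (0 and 1 adjusted over the list alone, list adjusted p = 0.79). Among reference genes 0 of 12 were higher and 0 lower (0 and 0 adjusted over the list alone, list adjusted p = 0.62). The leukocyte list passed without dim genes (adjusted p = 0.025), under median centring (0.032), without between-array normalization (0.017) and by fry (0.016). By fry the AP-1 (0.033), CDK inhibitor (0.0079) and reference lists (0.032) passed too. The AP-1 list passed with the position column as a block (0.047), and the G1/S and sterol lists under median centring (0.046 each). The AP-1 list holds both siRNA targets, JUN (1.15) and FOSL1 (-1.23), whose differences follow from the knockdowns themselves.

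The effects of the knockdowns were set side by side to see how far they overlapped. ADGRG6 (1.70 ± 0.07 with siFra-1 and 2.15 ± 0.07 with sic-Jun), CLCA2 (2.73 ± 0.17 and 2.07 ± 0.17), VDR (1.68 ± 0.11 and 1.70 ± 0.11), RGS5 (1.52 ± 0.12 and 2.79 ± 0.12) and PLEKHA6 (1.27 ± 0.08 and 1.25 ± 0.08) rose in both. NTRK2 (-1.40 ± 0.07 and -1.68 ± 0.07), SLC7A2 (-1.42 ± 0.10 and -1.66 ± 0.10), NPNT (-2.01 ± 0.09 and -1.34 ± 0.09), EOMES (-1.29 ± 0.10 and -1.36 ± 0.10) and PDGFRL (-1.13 ± 0.12 and -1.25 ± 0.12) fell in both. In all, 567 genes rose in both and 464 fell in both, against 58.7 and 64.95 for independent calls, and 48 were called in opposite directions, against 124. HBEGF (1.33 and -0.40), BGN (0.85 and -0.51), IGFBP4 (0.64 and -0.70), ELF3 (0.59 and -0.78), TGFB2 (0.46 and -0.38) and JUN were among the 48. Both comparisons used the same control arrays, which the expected numbers leave out of account. With the controls split into separate pairs 437 to 583 genes rose in both, 312 to 427 fell in both and 28 to 119 were called in opposite directions. The separate pairs still had the same control siRNA. A difference tied to that siRNA would appear in both comparisons, and the split cannot set it apart.

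Across 17958 genes, which are not independent replicates, the log2 fold changes of the knockdowns had a Pearson r of 0.63 and a Spearman correlation of 0.54. Simulated groups without effect gave a mean r of 0.43 from the shared controls, and the split controls gave r of 0.31 to 0.58. The 0.43 is no reference for the split controls, whose pairs share no array and were not simulated without effect. In simulations that kept the array-wide deviations, r ran from -0.84 to 0.96 and the covariance from -0.0209 to 0.0286 with a mean of 0.0047, so the observed r and covariance of 0.0269 lay inside the simulated range. With each array's deviations drawn once, r ran from -0.56 to 0.93 and the covariance from -0.0052 to 0.0213, so the observed r lay inside that range and the observed covariance above it. Genes were called in both comparisons in 0 and 1 of the 50 runs, so neither simulation gives a shared count at the observed number of calls. Of the 1031 genes that changed the same way in both, 127 (12.3%) also differed between the knockdowns. Of the 1139 called with siFra-1 alone 353 (31.0%) differed between the knockdowns, as did 280 (30.2%) of the 926 called with sic-Jun alone. The count of 1031 was 170 without between-array normalization, 522 with the position column as a block, 161 with a 1.5-fold minimum, 1579 with siControl replicates 2 and 3 averaged, 2958 with array weights and 1944 with arrays of position columns 7 and 9 alone. It was 643 without siFra-1 replicate 2, 661 without siFra-1 replicate 3 and 669 without sic-Jun replicate 2.

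**Figure D3:**
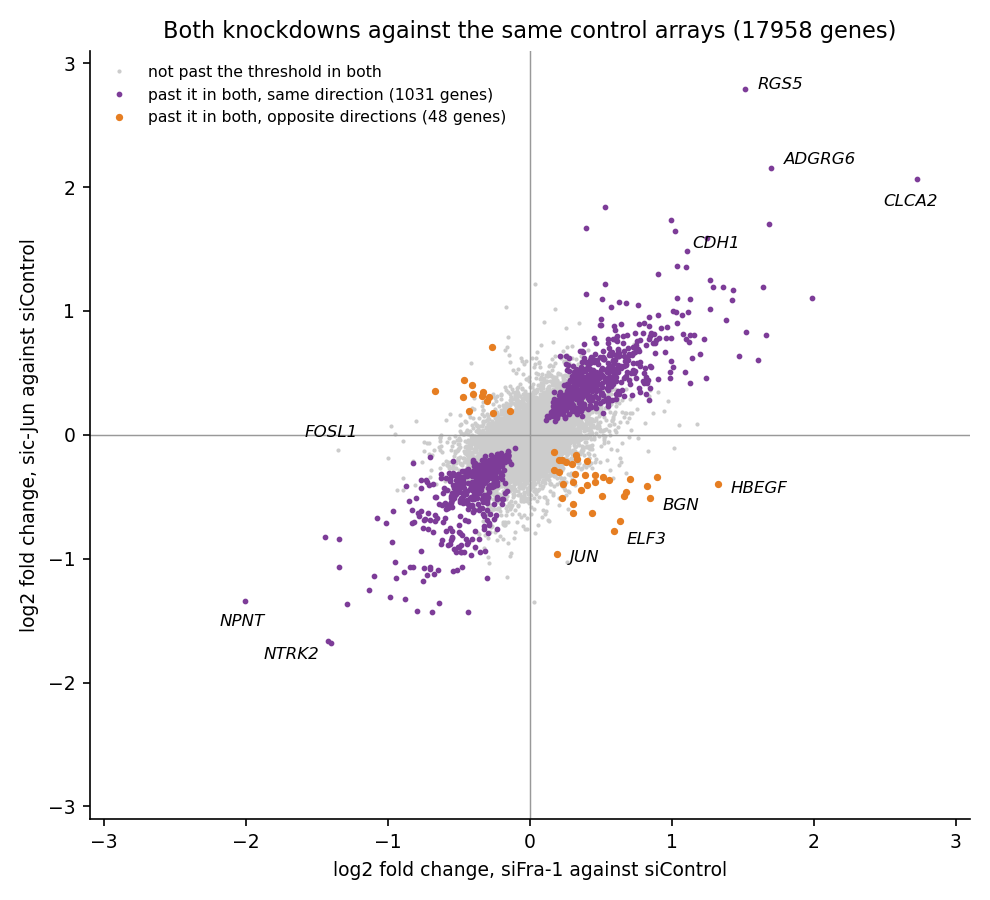
Log2 fold change of each of 17958 genes with siFra-1 (x axis) and with sic-Jun (y axis), each against the same 4 siControl arrays; purple points passed in both in the same direction and orange points in opposite directions. The 1031 purple genes lie along the diagonal and the 48 orange genes off it, with HBEGF, BGN and ELF3 higher with siFra-1 and lower with sic-Jun.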

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

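The test of the siRNA pools, the test of the position column and the simulations that drew each array's deviations once were chosen only after the results they address had been seen.

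In the 4 siControl arrays, the gap between the farthest array and its nearest neighbour was large against the group's range for 11 of 141 genes tested, where chance gives about 1 in 20 groups, or 7.05. Of the 11, 9 were in siControl replicate 3. Its log2 level was higher than in the other 3 arrays for JUNB (10.92 against 10.50 to 10.52), TRIB3 (8.24 against 8.04), COL1A1 (9.01 against 8.45 to 8.53), CD68 (9.75 against 9.35 to 9.41), DIO3 (8.82 against 8.43 to 8.47) and CDKN1B (10.76 against 10.64 to 10.66). It was lower for B2M (10.91 against 11.03 to 11.05), DNAJC3 (8.57 against 9.29 to 9.40) and HERPUD1 (10.00 against 10.07 to 10.08). PRLR was lower in siControl replicate 2 (10.06 against 10.14 to 10.15) and XBP1 in siControl replicate 1 (10.16 against 10.22 to 10.23).

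The 14116 probe sets that measured no gene or several genes were tested only in the fit of every probe set by itself. There 293 of them passed with siFra-1 against siControl (104 higher and 189 lower), 181 with sic-Jun against siControl and 95 between the knockdowns. These are 2.08%, 1.28% and 0.673% of them, against 8.43%, 7.15% and 3.22% of the probe sets of a single gene.

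The interferon list was higher in both knockdowns, with a median of 0.49 with siFra-1 and 0.45 with sic-Jun and 16 and 14 of 23 genes called, though the list did not pass with its estimated correlation of 0.31 (adjusted p = 0.060 and 0.17). The values of single arrays argue against control arrays that stand apart. The list's mean, minus the siControl mean, was 0.05 and 0.07 in siControl replicates 1 and 3. It was -0.03 and -0.09 in siControl replicates 2 and 4, 0.48 to 0.63 in siFra-1 and 0.44 to 0.59 in sic-Jun. The medians were 0.53 and 0.40 with arrays of position columns 7 and 9 alone. That setting left out siControl replicates 1 and 3 and sic-Jun replicate 1. Since siControl replicates 1 and 3 lay nearer the knockdowns than 2 and 4, these medians add little. The 16 and 14 called genes argue against a few genes carrying the list. Without its 4 largest members camera p was 6.7e-12 and 9.0e-11. These used the preset correlation of 0.01, far under the estimate of 0.31, and so add little. A response to double-stranded RNA from the targeting pools, in place of the loss of AP-1, may account for the rise of the list and stays open. The list rose alike with both pools (median difference 0.057, or -0.12 against -0.10 for all genes without between-array normalization; adjusted p = 0.79), but an effect of losing either AP-1 subunit would look the same, so the explanations cannot be told apart without other siRNAs or a rescue. The loss of AP-1 itself is an untested biological explanation.

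The deviations of arrays within groups were compared without the dimmest 30% of genes. Arrays of 1 group deviated from each other in common directions, and a single axis held 48.9% of the variance within groups. The position column may account for part of this: the gene-wise difference of siControl replicate 1 from 2 had r = 0.37 with that of 3 from 4, but the other pairing (1 from 4 with 3 from 2) gave r = 0.04, so it stays open. The brightness of the deposited array stays open too, with a Pearson r of 0.61 between the axis and the upper quartile over 10 arrays and a Spearman correlation of 0.66 (permutation p = 0.064 and 0.044, adjusted over 2 relations 0.064 for both); Pearson r was 0.54 without siControl replicates 1 and 4. The design names no biological difference within a group, so no biological explanation was tested.

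Splits of the same arrays were set beside the real grouping for the number of genes called with each knockdown, but they cannot exclude chance. A split that mixes the groups adds their difference to the spread within groups, which lowers its count. The smallest share that 35 splits can reach is 1 in 35. Of 35 splits of the 7 arrays, only the real one, 1 split, called as many genes: 2218 against at most 652 with siFra-1, and 2005 against at most 101 with sic-Jun. In both comparisons the highest other split moved siControl replicate 3 to the knockdown arrays. In 50 simulations without effect that kept the array-wide deviations, 1 run called as many genes with siFra-1 (7921) and 1 with sic-Jun (2526), where an array's deviations can be drawn more than once. With each array's deviations drawn once 0 of 50 runs did (at most 812 and 193). The 10 splits between the knockdowns are too few for such a share; the real one, the 1 split with that many genes, called 947 and the highest other 1.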

How the results depend on the processing

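No between-array normalization, arrays of position columns 7 and 9 alone, and the gene list tests under median centring and with a position block were chosen after the data were seen. The cause of the changes below was not tested unless the setting itself gives it.

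Counts of genes for siFra-1, for sic-Jun (each against siControl) and between the knockdowns stayed within 1.5 times 2218, 2005 and 947 without the mean-variance trend (1922, 1794, 842), with a robust fit (2236, 2038, 963), without dim genes (2462, 2289, 1098), with the mean of probe sets (2197, 1978, 941), with an offset of 1 (2212, 2009, 944), and with a block on the title number (1803, 1599, 771) or the description number (2020, 1765, 874). With every probe set by itself 1909, 1552 and 713 probe sets passed, which are not counts of genes. Of these, 293, 181 and 95 measured no gene or several genes. Without between-array normalization they were 284, 579 and 106, the overlap 170 and r 0.58; JUN with siFra-1 was 0.21 (adjusted p = 1.0) and FOSL1 with sic-Jun 0.091. There, with sic-Jun, ZEB1 (0.057), VIM (0.077), PLAUR (0.015) and FOXM1 (0.0008) reversed from called falls to rises that did not pass, beside a median of all genes of 0.09. Median centring gave 623 genes between the knockdowns, r 0.58, and JUN with siFra-1 at 0.22 (adjusted p = 0.068). With every probe set by itself r was 0.56. A 1.5-fold minimum, by its construction, left 340, 376 and 192 genes and an overlap of 161, and removed the call on JUN with siFra-1 (0.19). Fits of the compared groups alone gave 1221 with sic-Jun and 2084 between the knockdowns, and averaging siControl replicates 2 and 3 gave 1939 between the knockdowns and an overlap of 1579. The block on the title number left JUN with siFra-1 at 0.17 (adjusted p = 0.072). The position block, with sic-Jun replicate 1 left out, gave 962 genes with sic-Jun (1489 with siFra-1, 858 between the knockdowns), an overlap of 522 and FOSL1 with sic-Jun at 0.015. Array weights, from 0.115 for siControl replicate 3 to 43.1 for sic-Jun replicate 2, gave 4830, 7452 and 8486 genes and an overlap of 2958. Arrays of position columns 7 and 9 alone gave 4369, 3534 and 3639, an overlap of 1944 and FOSL1 with sic-Jun at 0.015.

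With an estimated inter-gene correlation 3, 0 and 0 of the 21 lists passed camera, in place of 11, 6 and 11. In that setting 6, 3 and 6 had an unadjusted p under 0.05. Fry, which asks whether a list shifted at all, passed 12, 8 and 13. The reference list was among them with siFra-1 (fry adjusted p = 0.0023). A pass by fry thus answers another question and does not make up for a call lost by camera. The estimated correlation of the interferon list was 0.31, against the preset 0.01.

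With 1 array of the compared groups left out at a time (the arrays of the other group stayed in the model), the counts ran from 1221 to 3340 with siFra-1, 1144 to 2779 with sic-Jun and 469 to 825 between the knockdowns, the overlap from 643 to 1540 and r from 0.54 to 0.67. The counts were lowest without a knockdown array in each case, and those of siFra-1, sic-Jun and the overlap were highest without siControl replicate 3. JUN with siFra-1 ran from 0.17 to 0.22 and lost its call without siFra-1 replicate 1 (adjusted p = 0.069), 2 (0.083) or 3 (0.052). FOSL1 with siFra-1 (-1.41 to -1.25) and JUN with sic-Jun (-0.98 to -0.93) passed throughout, and FOSL1 with sic-Jun ran from -0.18 to -0.02. Between the knockdowns FOSL1 ran from -1.26 to -1.21 and JUN from 1.14 to 1.16. The lists that passed numbered 10 to 11, 4 to 9 and 11 to 12.

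For single named genes, 1325 values with an array left out kept direction and call, 98 lost the call, 2 gained it and 3 moved; under the other settings these were 2779, 291, 22 and 9, with the 4 reversals above. For single lists the numbers were 397, 10, 6 and 7 with an array left out and 529, 49, 24 and 28 otherwise. The deviations of arrays from their group were correlated without the dimmest 30% of genes. Arrays with 1 title number in siControl and siFra-1 did not deviate alike (r -0.07, 0.06 and -0.27). Nor did those of siFra-1 and sic-Jun (0.13, 0.11 and -0.12). For siControl and sic-Jun r was 0.65, 0.28 and 0.0045. By the description numbers r was -0.07, 0.09 and 0.02 for siControl and siFra-1 and 0.65, 0.02 and 0.58 for siControl and sic-Jun. For description number 2, siControl replicates 2 and 3 were averaged, and their deviations had r = -0.80 with each other. Alone, replicate 2 had r = 0.28 and replicate 3 r = -0.14 with sic-Jun replicate 2. Since r was not above 0.1 in every pair of arrays, the numbers were not taken to pair them. A pairing of siControl with sic-Jun arrays stays open. Signal near background limits what can be said of dim genes, whose folds the offset of 16 shrinks.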

Other observations

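Families of genes with a common symbol root were tested after the data were seen, 323 families of at least 8 measured members, with camera and the preset correlation. With sic-Jun the metallothioneins were the family with the smallest p: 0 of 14 rose and 8 fell, with a median of -0.46 (adjusted p = 6.1e-06, but 0.997 with an estimated correlation). MT1F fell with sic-Jun (-1.18 ± 0.06, adjusted p = 1.1e-07), as did MT1X (-0.46 ± 0.06), MT1E (-0.40 ± 0.04) and MT2A (-0.20 ± 0.04). With siFra-1 1 member, MT1F, fell (-0.75 ± 0.06), and the family did not pass (adjusted p = 0.81). Metallothioneins bind zinc and copper. The median stayed negative under median centring (-0.41) and without between-array normalization (-0.26), where MT1X (adjusted p = 0.55), MT1E (0.66) and MT2A (0.94) did not pass. Without sic-Jun replicate 1 the median was -0.18 (adjusted p = 0.0084). Probes of such closely related genes can share signal, so how many members changed is uncertain.

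With siFra-1 the protocadherin beta cluster had the smallest p, with 0 of 18 members higher, 6 lower and a median of -0.21 (adjusted p = 6.9e-04, but 0.44 with an estimated correlation). PCDHB10 (-1.07 ± 0.12), PCDHB9 (-0.87 ± 0.09) and PCDHB2 (-0.64 ± 0.05) fell, and they fell with sic-Jun too (-0.67, -0.41 and -0.56), where the family did not pass (adjusted p = 0.34). The TMED cargo receptors of the early secretory pathway were higher with siFra-1 (5 of 10 higher, 0 lower, median 0.21, adjusted p = 0.010, but 0.998 with an estimated correlation), with TMED3 at 0.31 ± 0.04. The HOXB genes were lower (0 of 10 higher, 3 lower, median -0.19, adjusted p = 0.021, but 0.998 with an estimated correlation), with HOXB6 at -0.54 ± 0.06 and HOXB5 at -0.53 ± 0.09. These medians kept their sign under median centring (-0.19, 0.24 and -0.19) and without between-array normalization (-0.20, 0.23 and -0.20), where the TMED family (adjusted p = 0.089) and the single genes PCDHB2, TMED3, HOXB5 and HOXB6 did not pass. There the log2 fold changes of these single genes were -0.62, 0.33, -0.52 and -0.53.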
